A study of Mus musculus with 5 samples.

How the data were processed

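Viable CD45+ cells, the leukocytes, were sorted from the gastric corpus of C57B6/J mice, and the corpus tissue of 3 mice was combined for each library, per the labels' protocols. Libraries were made with the version 3 reagents of the 10x Genomics droplet system, with reagents calculated for 6000 cells, and sequenced on a NovaSeq. Reads were processed with Cell Ranger 3.0.1, per the labels' protocols, against genome build mm10, per the submitters' processing notes, which also name R 3.6.1 and Seurat 3.1.0. The deposited values are raw UMI counts (unique molecules) per gene and cell barcode, not normalized, in a matrix that Cell Ranger had filtered to barcodes called as cells. The other deposited tables hold barcodes and gene names and no measurement.

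The 5 libraries fall into 4 groups by their labels: 2 libraries of sham-operated males, 1 of sham-operated females, 1 of adrenalectomized (ADX) females and 1 of males with both the ADX and the castration label. A library is a pool of mice, so n counts libraries and p-values measure the spread between pools. The libraries held 6292, 6863, 5113, 8247 and 5795 barcodes in that order (sham_male replicate 1, sham_male replicate 2, sham_female replicate 2, ADX_female replicate 1, ADX_Cast_male replicate 1). The lowest UMI count of a barcode was 500 or 501 in each library, so cells of low RNA content are under-counted. As a check for 1 library deposited again under another name, the 2 sham male libraries were compared: they differed by more than counting noise in each of the 11 classes, with a chi-square per degree of freedom from 3.02 in eosinophil-like to 67.5 in macrophage-like cells. This shows no more than that they are not copies; they are separate replicates by their labels.

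Barcodes that occurred in more than 1 library were far more common within some pairs of libraries than others: 1820, 1093 and 1504 between pairs of sham_male replicate 1, ADX_female and ADX_Cast_male, 187 between sham_male replicate 2 and sham_female, and 4 to 19 in the other pairs. The first 3 libraries and the last 2 were therefore treated as 2 sequencing batches, a grouping read from the barcodes and not from the labels. A copy was kept only where it held at least 80% of a shared barcode's UMIs, which removed 4395 of 32310 barcodes. Cells with at least 300 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library from simulated doublets, and the barcodes with the highest scores were removed, a share that grew by 0.8 percentage points per 1000 barcodes, 1072 in all, which left 24556 cells.

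Cells of all libraries were clustered together (2000 variable genes without the response lists, 30 principal components, 20 neighbours, Leiden resolution 1.0) with Python 3.11.15, scikit-learn 1.9.0 and igraph 0.11.9, which gave 40 clusters. A cluster was named after the class with the highest marker score if that score was at least 1.0 and led the next class by 0.5, with at least 3 markers detected. Basophil scores counted as mast, and CD4 T, CD8 T and regulatory T cell scores as T. A merged partner was not counted as the next class. A cluster that met these limits still stayed unnamed where its top 10 genes by fold held more markers of another class than of its own, or where its cells' median UMI count was under 0.333 of their libraries' medians and fewer than 2 markers of its class were among those genes. These limits on the score were set after the data were seen; the markers were not. Of the clusters, 5 stayed unnamed, 3 for their leading genes, 1 for its low UMI count and 1 for having under 3 markers, and are given by number. Names are written as "X-like".

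UMIs were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in the 11 classes with at least 20 cells in every library. ADX against sham set 2 ADX libraries against 3 sham libraries with 3 residual degrees of freedom; 1 of the ADX libraries also has the castration label, so the fit measures what both share. A fit with 1 coefficient per group gave the sex-matched contrasts with 1 residual degree of freedom, in which groups of 1 library are assumed to vary like the sham males. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over 116 pairs of class and list. Cells per class were tested with edgeR, with kept cells as the library size. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only, and exact two-sided permutation tests, for which 3 against 2 libraries allow 10 arrangements and no p below 0.1. Nr3c1 was compared between classes with an exact two-sided sign-flip test over 5 libraries, which cannot go below 0.062, on log2 CPM with a prior of 0.5. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs.

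Genes were named by a rule set before the data were examined. Among genes past the threshold, with a mean log2 CPM of at least 4 and moving the same way in females and against each sham male library, the rule took the 5 with the largest rise and the 5 with the largest fall in ILC2-like cells, and 3 and 3 in each other class. Sex-linked genes, immune receptor segments, haemoglobins, mitochondrial, ribosomal and unnamed genes and the gastric epithelial list were left out. The same rule took 3 and 3 genes per sex-matched contrast in ILC2-like cells. Members of the 12 fixed lists could also be named. Gene positions come from GENCODE vM21 on the same build, in which 30766 of the 30828 gene IDs in the files were found.

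The tests were checked on simulated counts drawn from the real means, with 200 genes changed. For ADX against sham, a median over classes of 44.2% of genes changed by a fold of 2 and 92.9% of those changed by a fold of 4 were recovered, with 5.56% false calls (from 3.88 to 15.9%), on 2735 to 13179 genes. For a sex-matched contrast, 10.1% and 67.0% were recovered with 20.2% false calls (from 4.55 to 35.7%), well above the nominal 5%, on 2746 to 13208 genes. Calls in the sex-matched contrasts therefore hold more false positives than their threshold says. All simulated libraries shared a common mean per gene, without differences in sequencing batch, sex, cluster composition or free RNA. The false calls found in either comparison therefore leave out those that such differences give in the real libraries.

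Alternatives planned before the data were examined were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, sex as a covariate, stricter or no cell filters, doublets kept, other Leiden resolutions, each library clustered alone, another denominator, an estimated correlation in camera, no thinning, and leaving out each library. Alternatives added after seeing the data were shared barcodes kept, clusters of low UMI count left out, the sequencing batch as a covariate, and the first sequencing batch alone. Both ADX libraries were in the first batch and the other batch held sham libraries only. Both batch alternatives therefore measure the ADX effect against sham_male replicate 1 alone. Results for some genes are not reported here.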

Results

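The series addresses how glucocorticoids and androgens act on group 2 innate lymphoid cells (ILC2) and gastric inflammation, as its title states. Adrenalectomy removes the source of circulating glucocorticoids, and castration the main source of androgens. Single-cell RNA counts of sorted gastric leukocytes were available from 5 libraries of 3 pooled mice each: 3 sham libraries (2 male, 1 female), 1 ADX female library and 1 library of castrated ADX males (ADX_Cast_male). After filtering, 4313, 5633, 4417, 5816 and 4377 cells were kept (sham_male replicates 1 and 2, sham_female, ADX_female, ADX_Cast_male), with a total of 78780523, 115832546, 91101067, 92218686 and 56344097 UMIs before filtering and a median of 14106, 12905, 14051, 8505 and 7843 UMIs per kept cell. Xist, expressed from the inactive X chromosome of females, was at 1050 and 868 CPM in the female libraries and at 0.31, 10.5 and 0.179 CPM in the male ones, and the Y-linked gene Ddx3y at 0.016 and 0.118 CPM in the female libraries and 157, 179 and 150 CPM in the male ones, so the sex of each library matched its label. CPM stands for UMI counts scaled to the total of the library or of its class.

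By share of kept cells, the ADX libraries held more plasma, mast, B and eosinophil-like cells and fewer macrophage and monocyte-like cells than the sham libraries. Shares are relative, so the fall of the largest class, macrophage-like cells, raises the shares of the others. Numbers of cells in the tissue were not measured. Plasma-like cells made up 0.232% ± 0.107 (SD, n = 3) of sham and 7.64% ± 2.82 (n = 2) of ADX cells, mast-like cells 2.49% ± 0.116 and 16.3% ± 7.42, B-like cells 0.483% ± 0.108 and 3.6% ± 3.12, and eosinophil-like cells 4.04% ± 2.15 and 13.5% ± 5.23. Macrophage-like cells, without the unnamed clusters described below, fell from 43.5% ± 4.42 to 11.7% ± 1.44 and monocyte-like cells from 4.50% ± 0.733 to 2.04% ± 0.116. In edgeR's test the adjusted p was 3.93e-04 for plasma, 0.00177 for mast, 0.00403 for macrophage, 0.0093 for B, 0.0235 for eosinophil and 0.0235 for monocyte-like cells; the exact permutation p was 0.1 for each, the smallest that 3 against 2 libraries allow. Epithelial-like (adjusted p = 0.013) and endothelial-like cells (adjusted p = 0.00989), which the CD45 sort should remove, were also fewer. Endothelial-like cells numbered only 4, 10 and 9 in the sham and 1 and 1 in the ADX libraries. Stromal-like cells, which the sort should remove too, numbered 206, 22 and 84 in the sham and 0 and 25 in the ADX libraries. Their share did not pass (edgeR adjusted p = 0.274). ILC2-like cells were 8.79% ± 3.51 of sham and 9.55% ± 2.07 of ADX cells, a difference within the spread between libraries (log2 ratio 0.12, SE 0.44, edgeR adjusted p = 0.794). Eosinophil-like cells held a median of 687 UMIs, so the lower UMI limit of the files and the minimum of 300 genes can set part of their share. Plasma and mast-like cells passed in every alternative run (15 and 16). Macrophage-like cells lost the call in 1 of 16, with shared barcodes kept (log2 ratio −0.89, edgeR adjusted p = 0.121; range over alternatives 1.48e-04 to 0.121), and monocyte-like cells in 9 of 15 (edgeR adjusted p from 0.0112 to 0.125), among them without sham_male replicate 1 (−1.08), sham_female (−1.06), ADX_female (−1.08) or ADX_Cast_male (−1.20). B-like cells lost it in 3 of 15, with the sequencing batch as a covariate and without sham_male replicate 2 (2.74) or ADX_female (1.53). Eosinophil-like cells lost it in 4 of 13, with the batch and without sham_male replicate 2 (1.47), ADX_female (2.09) or ADX_Cast_male (1.29). No eosinophil-like class was found under the stricter cell filter or without low-UMI clusters. With each library clustered alone it was found in the ADX libraries only. These alternatives are not among the 13. The batch covariate, chosen after seeing the data, ended 5 of the share calls. Its log2 ratio was 2.88 for B (edgeR adjusted p = 0.0627; range over alternatives 1.15e-04 to 0.0868), 2.03 for eosinophil (0.0627; 4.89e-04 to 0.173), −1.26 for monocyte (0.0627), −1.67 for epithelial (0.0574; 8.11e-04 to 0.119) and −2.10 for endothelial-like cells (0.106; 0.00203 to 0.106). The epithelial and endothelial log2 ratios of −2.49 and −2.86 shrank to −0.96 and −1.50 with shared barcodes kept, where both calls ended (edgeR adjusted p = 0.119 and 0.105). They were −1.33 and −1.39 with doublets kept, where the endothelial call ended (edgeR adjusted p = 0.0738). Epithelial-like cells lost the call in 5 of 14 alternatives, among them also without sham_male replicate 2 (−2.26) or ADX_female (−1.92). Endothelial-like cells lost it in 6 of 14, among them also without sham_male replicate 2 (−2.76), ADX_female (−2.66) or ADX_Cast_male (−3.04).

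**Figure D1:**
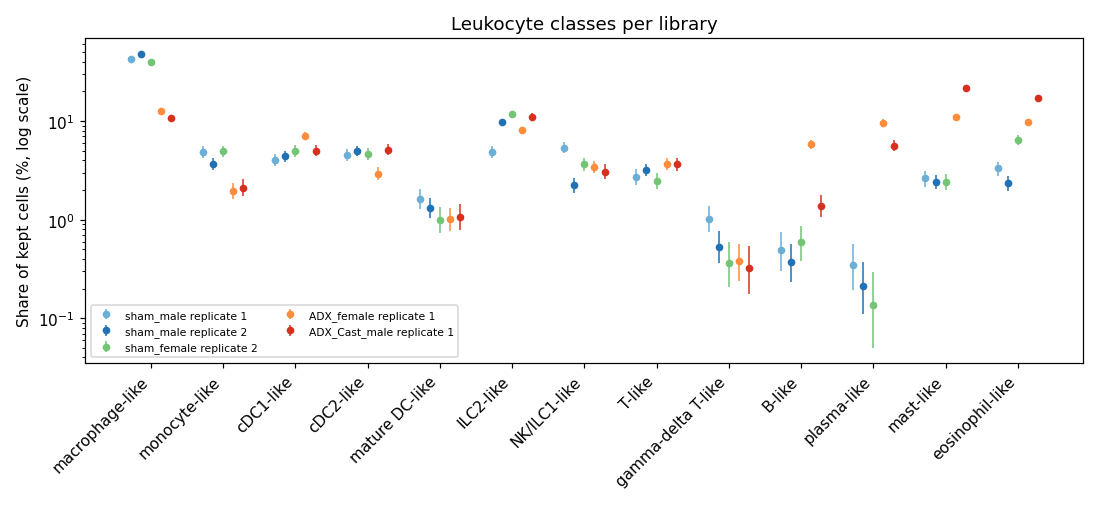
Share of kept cells (percent, log axis) in 13 leukocyte classes, 1 point per library with its exact 95% binomial interval. Macrophage-like cells lie at 12.7% and 10.7% in the ADX libraries, below 39.4% in the lowest sham library, and plasma-like cells at 9.63% and 5.64%, above 0.348% in the highest.

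Clusters that scored highest for macrophage markers but stayed unnamed moved in different directions. Clusters 6, 7 and 17 were left unnamed because their top 10 genes held a marker of another class and 0 of macrophages. This marker was Apol7c (mature DC) in cluster 6, F13a1 (monocyte) in cluster 7 and Atp4b (epithelial) in cluster 17. Named macrophage-like clusters 0, 1, 3 and 25 held 0 macrophage markers among their top 10 genes too, so the naming turned on such a gene. Cluster 12 stayed unnamed because of its few UMIs. Cluster 6, led by Pgf, Gpnmb and Mmp12, made up 2.07% ± 1.05 of sham and 7.23% ± 2.12 of ADX cells. Cluster 7, led by Lyve1, Cd209f and Folr2, genes of perivascular macrophages, made up 5.82% ± 3.70 and 1.84% ± 1.19. Cluster 12, with few UMIs per cell, made up 0.81% ± 0.411 and 6.6% ± 4.94. Cluster 17, led by parietal cell genes such as Atp4b, made up 3.2% ± 2.53 and 0.123% ± 0.0448. Cluster 23, the other unnamed cluster, scored highest for erythroid markers but had under 3 of them detected. It was led by Pla2g1b, Clps and Chia1 and made up 1.29% ± 0.798 and 0.349% ± 0.153. The exact permutation p was 0.1, 0.3, 0.1, 0.2 and 0.3. The fall of the macrophage-like class holds for the named clusters, and counting clusters 6, 7, 12 and 17 with them would make it smaller. With each library clustered alone, ADX_female held 1421 macrophage-like cells against 739 in the joint clustering, and ADX_Cast_male 621 against 467. The sham libraries held 1972, 2865 and 1950 against 1852, 2715 and 1741.

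Nr3c1 was highest in ILC2-like cells among the 11 classes. This gene, which encodes the glucocorticoid receptor (ENSMUSG00000024431.14, chromosome 18, 39410545 to 39519421, minus strand), averaged 627 CPM ± 165 (SD, n = 5) in ILC2-like cells, 320 ± 40.0 in T-like, 224 ± 32.2 in NK/ILC1-like, 157 ± 29.1 in mast-like and 103 ± 19.0 in macrophage-like cells. It was higher in ILC2-like cells than in each of the 10 other classes in 5 of 5 libraries, with the smallest exact sign-flip p that 5 libraries allow, 0.062, in each of the 10 tests and the same value after adjustment. The narrowest margin, over T-like cells, was 0.94 on the log2 scale.

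**Figure D2:**
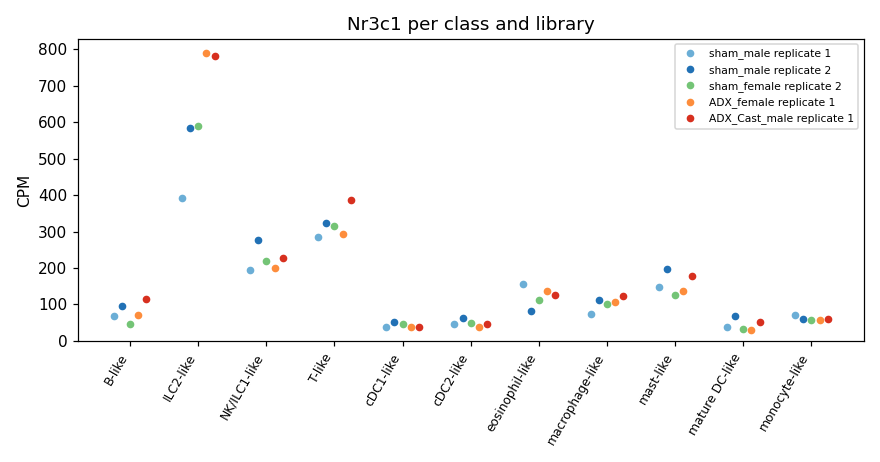
Nr3c1 in CPM per class, 1 point per library, on a linear axis. ILC2-like cells hold the highest mean, 627 CPM.

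Nearly every ILC2-like cell carried a transcript of at least 1 of the genes Il13, Il5, Csf2, Il4 and Areg, in sham and ADX libraries alike. Shares of the single genes can be lower than this joint share. After thinning to 2000 UMIs, 93.3% (95% interval 88.9 to 96.4), 91.6% (88.9 to 93.8) and 94.0% (91.6 to 95.9) of ILC2-like cells in the sham libraries and 92.7% (89.9 to 95.0) and 93.5% (90.9 to 95.6) in ADX_female and ADX_Cast_male held a UMI of Il13, Il5, Csf2, Il4 or Areg; 16, 16, 1, 31 and 20 shallower cells were left out. In B-like cells, which should lack these genes, the shares were 0.0%, 4.76% and 0.0% of 21, 21 and 24 sham cells and 4.22% and 1.85% of 332 and 54 ADX cells. Unthinned, the shares in ILC2-like cells were 96.7%, 97.5%, 99.6%, 97.2% and 97.5%. The median depth was 8626, 7553, 9278, 9440.5 and 9938.5 UMIs in ILC2-like cells and 5217, 5940, 5387, 7340.5 and 5532 in B-like cells. A share this close to its ceiling cannot show a rise.

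In ILC2-like cells, ADX against sham called 650 of 10184 genes, with 406 higher and 244 lower in ADX. With the sequencing batch as a covariate 111 were higher and 121 lower. The largest rises were of Cald1, an actin-binding protein, from 2.33 to 209 CPM (log2 fold change 6.42, SE 0.74, adjusted p = 0.025), Dusp4, a phosphatase of MAP kinases (2.89), Gclc, which makes the first intermediate of glutathione (2.78), Hmgn3 (2.65) and the amino acid transporter Slc38a5 (2.65). Cald1 was not particular to this class: it also rose in T-like cells (5.45, SE 0.48, edgeR adjusted p = 4.43e-06). Stromal-like cells held it at 8.26 times the level of ILC2-like cells. The largest falls were of Dtx1, a regulator of Notch signalling (−3.25, SE 0.54, adjusted p = 0.0164), Ly6a (−2.33), the polarity gene Pard3 (−2.16), the chemokine Cxcl1 (−2.00) and Lilrb4a (−2.00). Of 24 type 2 lymphocyte activation genes, Lif rose (1.45), Areg (−0.61) and Klrg1 (−1.19) fell and 21 did not pass; over the list alone 1 was higher and 7 lower, and the list as a whole did not pass (adjusted p = 0.748). Il13 (0.17, SE 0.26) and Il5 (−0.04, SE 0.25) did not pass. Of 15 inflammatory cytokine genes 6 fell, among them Cxcl1, Cxcl3 (−1.49) and Ccl7 (−1.89), and Ptgs2 rose (1.46); the list was lower (camera adjusted p = 9.63e-06, adjusted p = 0.356 with an estimated correlation). Of 19 early response and heat shock genes 11 fell, among them Dnajb1 (−1.79), Egr1 (−1.33) and Jun (−1.06) (camera adjusted p = 2.01e-09, adjusted p = 0.425 with an estimated correlation). Igkc, an immunoglobulin gene of plasma and B cells, was higher in the ADX libraries in ILC2-like cells too (5.11, SE 0.23, edgeR adjusted p = 1.06e-08), so transcripts of other cells are among the genes called; it was chosen after its values were seen. Clusters 4 and 15 held most ILC2-like cells of the sham libraries, while cluster 19 held 41.1% and 33.2% of those in ADX_female and ADX_Cast_male against 1.90%, 1.82% and 8.90% in the sham libraries. Cluster 19 was led by Il17a, Akap12, Il17f and Il13, with 1 ILC2 marker among its top 10 genes. The fit does not tell a shift between these clusters from changes within them. With the sequencing batch as a covariate 232 genes were called, 183 of them among the 650, and the calls of Cald1 (6.50), Hmgn3 (3.15), Slc38a5 (2.32), Dtx1 (−3.18) and Pard3 (−2.33) were lost at folds close to those without it, while those of Dusp4, Gclc, Ly6a, Cxcl1 and Lilrb4a passed in all alternatives. Leaving out 1 library gave 363 (without sham_male replicate 2), 389 (without ADX_female) and up to 1147 genes (without sham_female), and Cald1 lost its call without sham_male replicate 1 (6.41) or sham_female (7.26), Dtx1 without sham_male replicate 1 (−3.27) or ADX_female (−2.75), Slc38a5 without sham_male replicate 1 (2.75) and Pard3 without sham_male replicate 1 (−2.07), ADX_female (−1.96) or ADX_Cast_male (−2.40).

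Tsc22d3, which encodes the glucocorticoid-induced leucine zipper GILZ (ENSMUSG00000031431.13, chromosome X, 140539528 to 140600659, minus strand), was lower in ADX in each of the 11 classes and passed the test in 7. It fell from 253.8 to 122 CPM in NK/ILC1-like cells (log2 fold change −1.05, SE 0.17, edgeR adjusted p = 3.84e-04), from 66.2 to 31.8 in ILC2-like cells (−1.05, SE 0.19, adjusted p = 0.00231) and from 196.8 to 95.9 in macrophage-like cells (−1.04, SE 0.14, adjusted p = 0.0199). It did not pass in B, eosinophil, mature DC and monocyte-like cells, with the smallest difference in eosinophil-like cells (−0.15, SE 0.30). Fkbp5, another direct target of the receptor, fell in ILC2-like cells (−1.22, SE 0.26, adjusted p = 0.0138), 1 of the 9 classes in which it was measured, and Cd163, a scavenger receptor, in macrophage-like cells (−1.42, SE 0.15, adjusted p = 0.00515). In macrophage-like cells Tsc22d3 lost its call in 3 of 17 alternatives and Cd163 in 4, both without ADX_female (−1.08 and −1.49) or ADX_Cast_male (−0.997 and −1.36), where 1 ADX library was left. The other loss of Tsc22d3 came with the sequencing batch as a covariate (−0.81, edgeR adjusted p = 0.0756; range 1.42e-08 to 0.31). Those of Cd163 came under the stricter cell filter (−0.78, edgeR adjusted p = 0.256; range 1.68e-12 to 0.256) and with shared barcodes kept (−0.98, edgeR adjusted p = 0.179). Other members of the glucocorticoid-induced list moved the other way: Ndrg1 rose in cDC1 (1.69), mature DC (1.34) and monocyte-like cells (0.98) and fell in mast-like cells (−1.54). Il1r2 was fitted higher in 10 of 10 classes and passed in mast-like cells (1.40). In cDC1-like cells Ndrg1, Txnip (0.60) and Errfi1 (0.67) rose and Tsc22d3 (−1.04) fell. As a whole the list of 25 glucocorticoid-induced genes was lower in 3 of 11 classes, B, T and mast-like (camera adjusted p = 2.84e-04, 0.0163 and 0.0265, and adjusted p = 0.425, 0.469 and 0.585 with an estimated correlation). In ILC2-like cells Tsc22d3, Fkbp5, Cxcr4 and Btg1 fell, Bcl6 rose (0.93) and the list did not pass in the fit without a batch covariate (camera adjusted p = 0.187). With the sequencing batch as a covariate the list was lower in 6 of 11 classes.

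**Figure D3:**
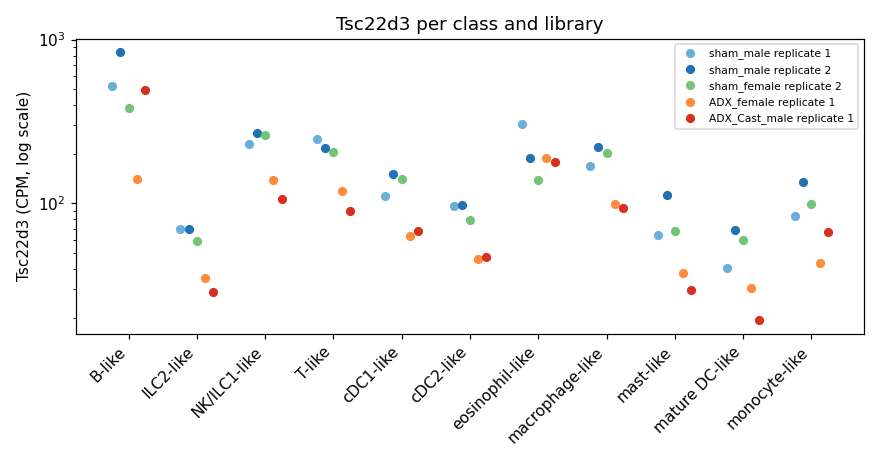
Tsc22d3 in TMM-scaled CPM (log axis) in 11 classes, 1 point per library. In ILC2-like cells the sham libraries average 66.2 CPM and the ADX libraries 31.8 CPM.

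In mast-like cells, a class that also takes in clusters scoring highest for basophil markers, 74 genes rose and 262 fell of 8467. Among the largest falls were those of Mrgprb1, a receptor of connective tissue mast cells (−4.90, SE 0.38, adjusted p = 3.67e-05) and Chst1 (−4.44), and the largest rises were of Nxpe4 (2.23), Itgb3 (1.92) and Zbtb37 (1.77). Tnf (−2.27), Ccl7 (−3.21), Il13 (−1.36) and Il3 (−4.30) fell as well; the inflammatory cytokine list was lower with 5 of 13 members called (camera adjusted p = 2.50e-08, adjusted p = 0.356 with an estimated correlation). Different clusters held the class in the 2 kinds of library: cluster 5 held 66.2% and 57.8% of mast-like cells in the ADX libraries, and cluster 16 held 48.7%, 58.8% and 56.1% in the sham libraries. Cluster 16 had the basophil marker Mcpt8 among its leading genes. Cluster 36, led by Mcpt4 and Mrgprb1 and scoring highest for basophil markers, held 9.73%, 22.8% and 11.2% of sham and 0.469% and 0.425% of ADX mast-like cells. The fit does not tell a shift between these clusters from changes within them. The fall of Mrgprb1 can therefore reflect the smaller part of cluster 36 in the class. Leaving out 1 library gave 92 (without ADX_female), 125 (without ADX_Cast_male), 207 (without sham_male replicate 2), 592 (without sham_male replicate 1) and 692 genes (without sham_female). Zbtb37 lost its call without ADX_Cast_male (1.73), and with the sequencing batch as a covariate Zbtb37 (1.25) and Nxpe4 (1.62) lost theirs.

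In cDC1-like cells 148 genes rose, among them Apol7c (2.29, SE 0.13, adjusted p = 8.02e-07) and Clec10a (2.15), which was 10.6 times higher in cDC2-like cells, and 76 fell, among them the lectin Cd207 (−2.47, SE 0.19, adjusted p = 8.41e-06). With the sequencing batch as a covariate 98 rose and 129 fell. Cluster 22, with a median of 752 UMIs per cell, held 44.5% and 22.3% of cDC1-like cells in ADX_female and ADX_Cast_male against 9.14%, 2.42% and 1.82% in the sham libraries. The median depth of the class was 9987 and 28166 UMIs in the ADX libraries against 29214, 27626.5 and 28086.5. In mature DC-like cells Il6 rose (2.39), a gene 10.5 times higher in eosinophil-like cells, with the chemokines Ccl22 (1.40) and Ccl17 (0.73), while Ccl5 fell from 4655 to 843 CPM (−2.46, SE 0.38, adjusted p = 0.0363). The call of Ccl5 was lost in 8 of 17 alternatives, among them with the sequencing batch as a covariate (−2.39) and without ADX_female (−2.92) or ADX_Cast_male (−2.12). That of Il6 was lost in 7 of 17, among them with the batch (2.80) and without sham_male replicate 1 (2.16), sham_female (2.33) or ADX_Cast_male (1.40). Of cDC1-like cells the count was 224 genes, or 751 without sham_male replicate 1, 137 without sham_female and 49 without ADX_Cast_male. Of mature DC-like cells it was 136, or 74 without sham_male replicate 2, 77 without sham_female, 214 without ADX_female and 67 without ADX_Cast_male. The alternative activation list was higher in both classes (camera adjusted p = 0.0175 and 0.0482, and adjusted p = 0.515 for each with an estimated correlation). With the sequencing batch as a covariate neither call held (camera adjusted p = 0.333 and 0.224). In cDC2-like cells 64 genes rose, led by Tcea3 (2.10), Ston2 (1.52) and Plet1 (1.43), and 54 fell; the count was 46 without sham_male replicate 2, 178 without sham_female, 198 without ADX_female and 16 without ADX_Cast_male, where Ston2 (1.32) and Plet1 (1.30) lost their calls, as Ston2 did with the batch covariate (1.51). In monocyte-like cells the elastase Mmp12 rose from 641.5 to 1609 CPM (1.33, SE 0.12, edgeR adjusted p = 1.75e-04), among 43 genes called. Mmp12 and H2-M2 were also leading genes of unnamed clusters 6 and 12, and Apol7c of cluster 6. Both clusters made up more of the ADX cells and were left out when levels were compared between classes. RNA from their cells was therefore not told apart from a rise of these genes within the named classes. In macrophage-like cells 20 genes rose, among them H2-M2 (1.09) and Lag3 (0.78), and 6 fell of 13368; without sham_male replicate 1 the count was 463, and without ADX_Cast_male 7. H2-M2 and Lag3 lost their calls in 7 and 5 of 17 alternatives, among them with the sequencing batch as a covariate (0.83 and 0.75) and without sham_male replicate 2 (0.975 and 0.75), ADX_female (0.968 and 0.78) or ADX_Cast_male (1.21 and 0.77).

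In T-like cells the NK receptor genes Klra1 (−2.47, SE 0.27, adjusted p = 4.45e-05) and Klre1 (−2.25) and the cytokine Csf2 (−2.58) fell, among 30 higher and 42 lower genes. Csf2 was 15.7 times higher in ILC2-like cells and lost its call in 6 of 17 alternatives: with shared barcodes kept (−0.32, edgeR adjusted p = 0.982; range 6.49e-17 to 0.982), each library clustered alone (−1.32), the stricter cell filter (−2.78), and without sham_male replicate 2 (−2.55), ADX_female (−2.57) or ADX_Cast_male (−2.60). Klra1 (−3.91) and Klre1 (−2.28) lost theirs with each library clustered alone, and Klre1 also within the first batch (−1.90). The count of 72 genes in T-like cells was 35 without sham_male replicate 2, 155 without sham_female and 31 without ADX_Cast_male. In NK/ILC1-like cells the chemokines Ccl5 (−1.80) and Ccl4 (−1.81) fell, and Fbxo32 (1.25) and Abcb1b (1.05) rose, among 16 higher and 35 lower genes. The count was 86 without sham_male replicate 1, 81 without sham_female and 115 without ADX_female; Fbxo32 lost its call without sham_male replicate 1 (0.93) or ADX_Cast_male (1.00), and Abcb1b without ADX_Cast_male (0.89). The T cell effector list was lower in both (camera adjusted p = 0.00308 and 1.87e-04, and adjusted p = 0.527 and 0.356 with an estimated correlation); within the first batch the call in T-like cells ended (camera adjusted p = 0.135). In eosinophil-like cells 38 genes rose and 70 fell, Tlr2 (−2.15) among the latter, and in B-like cells 3 rose and 8 fell, Fos (−2.07) among the latter. Tlr2 lost its call with the sequencing batch as a covariate (−1.47) and within the first batch (−1.45). Fos lost its call with doublets kept (−1.27), at Leiden resolution 2 (−1.81) and within the first batch (−1.48). The eosinophil count was 41 without sham_male replicate 2, 46 without sham_female and 53 without ADX_Cast_male, and the B count 29 without sham_male replicate 1, 23 without ADX_female and 38 without ADX_Cast_male. Several of the largest differences were of genes that other cells held at far higher levels: Mcpt2 rose in T-like (2.99) and NK/ILC1-like cells (2.70) and was 593 and 894 times higher in mast-like cells, Mzb1 rose in eosinophil-like cells (4.51) and was 21.9 times higher in plasma-like cells (4.50, 4.57 and 4.47 without sham_male replicate 1, sham_male replicate 2 and sham_female, where its call was lost), and Apoe (−1.66) and C1qb (−1.64) fell in cDC2-like cells and were 63.8 and 63.4 times higher in macrophage-like cells. Apoe lost its call with doublets kept (−1.40), with the batch covariate (−1.78) and without sham_male replicate 1 (−1.59) or sham_male replicate 2 (−1.60).

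Early response and heat shock genes were lower in ADX in all 11 classes (camera adjusted p from 6.65e-12 in mast-like to 0.00669 in macrophage-like cells). No class passed with an estimated correlation, where the lowest adjusted p was 0.356. Without ADX_Cast_male 10 classes passed, and macrophage-like cells did not. Fos was called lower in 5 classes, Jun and Hspa1a in 4 each, and no member was called higher in any. Inflammatory cytokine genes were lower in 9 of 11 classes and gastric epithelial transcripts, which leukocytes do not make, in 8 of 10, and neither list passed in any class with an estimated correlation (lowest adjusted p = 0.356 and 0.425). With the sequencing batch as a covariate these lists were lower in 11, 7 and 2 classes, and within the first batch in 11, 8 and 3. Proliferation genes were lower in macrophage and monocyte-like cells (camera adjusted p = 2.59e-05 and 5.82e-05, and adjusted p = 0.467 and 0.425 with an estimated correlation), although no single member passed over all genes, and 8 and 3 members were lower when adjusted over the list alone. A fit with the batch as a covariate kept the proliferation list lower in both and had it higher in T-like (camera adjusted p = 0.0293) and mast-like cells (camera adjusted p = 3.41e-05); in mast-like cells its direction without the covariate was lower (camera adjusted p = 0.149).

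Sex-matched contrasts in ILC2-like cells rest on 1 residual degree of freedom, and the simulated excess of false calls applies to them. ADX_female against sham_female called 331 genes higher and 173 lower, and ADX_Cast_male against sham_male 612 higher and 457 lower. Called in both were 226 higher genes, where independent lists would share 19.9, and 88 lower genes, where they would share 7.76; DESeq2 called 53 and 202 genes in the 2 contrasts. ADX_female and sham_female were of different sequencing batches, and so were ADX_Cast_male and 1 of the sham_male libraries, so the overlap of independent lists leaves out a batch difference that both contrasts can hold. Both contrasts also use the same variance estimate per gene, so genes with a low estimate can pass in both together. The numbers for independent lists are therefore too low as a reference. Cald1 (6.30 in females, 6.43 in males) and Kmo, an enzyme of tryptophan breakdown (2.94 and 4.70), rose in both. Ly6c1 had 0 UMIs in ADX_female and 2 in ADX_Cast_male, against 9 in sham_female and 103 and 300 in the sham_male libraries. Sham_female against sham_male called 140 genes higher and 106 lower. Il9 was at 427 CPM (95% Poisson interval 410 to 445) in sham_female and at 1.07 and 3.92 CPM in the sham_male libraries (log2 difference 7.22). The p-value of that gene rests on a single sham female library and is not given here. Ctla4 was likewise higher in sham_female (3.34), and Ly6c1 (−5.14) and the chemokine receptor Ccr9 (−2.73) were lower.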

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

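The tests of explanations in this part were chosen after the results were seen. In ILC2-like cells, the effect in females (ADX_female minus sham_female) and in males (ADX_Cast_male minus sham_male) differed by a test of the difference itself for 114 genes in edgeR, with 1 residual degree of freedom, and for 3 genes in DESeq2. By the fixed rule the largest were Gadd45g (2.42), Phlda1 (2.27) and Dach2 (2.25), higher in the female contrast, and Il9 (−9.71), Dppa2 (−4.17) and Hopx (−2.88), lower in it, each as a difference of log2 fold changes. Each contrast sets 1 treated library against its shams, and the male one adds castration, and ADX_female and sham_female are of different sequencing batches, so sex, castration, sequencing batch and single-library differences cannot be told apart.

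Signals of the other sex appeared in the copies of shared barcodes that were removed for holding too small a share of the barcode's UMIs. In ADX_female these held Y-linked UMIs at 93.18 CPM, against 0.78 in barcodes found in that library only. In sham_female they held 2.88 CPM, from 1 UMI, against 0.15. In the male libraries they held Xist at 282.01 CPM (sham_male replicate 1), 122.28 CPM (sham_male replicate 2) and 454.39 CPM (ADX_Cast_male), against 0.48, 10.04 and 0.0 in barcodes found in 1 library.

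Early response and heat shock transcripts were lower in the ADX libraries in all 11 classes by camera with a preset correlation (10 without ADX_Cast_male), but no class passed with an estimated correlation (adjusted p from 0.356 to 0.515). A sequencing batch effect as the whole cause is argued against by the first batch. There the list's mean log2 difference was below −0.1 in 11 of 11 classes. In the fit with batch as a covariate the list stayed lower in 11 of 11. That fit measures the ADX effect against the same sham library, sham_male replicate 1, so it is no separate evidence. Free RNA from other cells is argued against by the members that a class itself holds at a level comparable with the highest class, whose median log2 fold change over classes was −0.525. Different handling of the cell suspensions stays open: both ADX libraries lay below every sham library in 11 of 11 classes, which handling and surgery would each give, and digestion itself may induce these genes.

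Pgc and Chia1, genes of chief cells, were lower in most leukocyte classes of the ADX libraries: in edgeR Pgc was called lower in 8 of 11 classes (5 without ADX_female and 5 without ADX_Cast_male) and Chia1 in 6 of 10, and in ILC2-like cells Pgc was at 81.5, 164 and 129 CPM in sham and 19.8 and 20.0 CPM in ADX. The cDC1-like cells of ADX_Cast_male were an exception, with 717 CPM of Pgc and 201 CPM of Chia1 against 128 to 767 and 19.8 to 65.1 CPM in sham. A sequencing batch effect as the whole cause for Pgc and Chia1 is argued against by the first batch. There the median log2 difference of their sum over classes was −1.90 in ADX_female and −1.70 in ADX_Cast_male, beyond the range of 0.95 between sham libraries. With batch as a covariate Pgc was called lower in 7 classes and Chia1 in 5. That fit measures the ADX effect against the same sham library, sham_male replicate 1, so it is no separate evidence. The gastric epithelial list as a whole, of which both are members, was lower in 8 of 10 classes without the covariate and in 2 with it. Fewer epithelial cells in the suspension should lower mucous and pit cell transcripts by as much: the median gap between both falls was −2.63 in females and −1.91 against sham_male replicate 1, beyond the range of 1.51 between sham libraries, but −0.51 against sham_male replicate 2, which lies within it, so this stays open. Fewer chief cells alone, or less of these transcripts in them after the surgery, were not tested and stay open too.

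Il17a in ILC2-like cells was at 64.9, 4.84 and 159 CPM in the sham libraries and at 1716 and 954 CPM in ADX_female and ADX_Cast_male, but the difference did not pass in edgeR (log2 3.95, SE 1.55, adjusted p = 0.324). Il17a led cluster 19, which held a larger part of this class in the ADX libraries. A shift towards this cluster and a rise within clusters were not told apart. Of 180 ADX cells of the class with at least 2 Il17a UMIs, 0 held a UMI of Trdc, a gamma-delta T cell receptor gene (up to 2.03%). Among gamma-delta T-like cells 69.8% (at least 61.0) held one. Trdc was also a marker that named the gamma-delta T-like class, so its absence here was partly set in advance. It therefore cannot exclude such cells in the class. The Cd3 share of the 180 cells, 33.3% (26.5 to 40.7) against 100.0%, did not clear the bound first set for it and was set aside. That share lay above the 12.7% (10.3 to 15.3) of ADX cells of the class with no Il17a UMI. Free RNA is argued against by the thinned share of cells with an Il17a UMI, whose lower bound was 18.9% and 10.8% in the ADX libraries against upper bounds of 3.06% and 6.6% in B-like cells. Of the 180 cells 98.9% held Il13, 99.4% Gata3 and 98.3% Il17rb, and after thinning to 2000 UMIs 90.4% (85.1 to 94.3) held Il13, against 59.4% (55.6 to 63.1) of ADX cells of the class with no Il17a UMI, 7.33% (4.80 to 10.6) of ADX T-like and 1.68% (0.204 to 5.94) of gamma-delta T-like cells (unthinned 74.3%, 14.2% and 4.76%), so T cells without type 2 transcripts could not make up the set. Gata3 and Il17rb were among the markers that named the ILC2-like class, so their shares are no separate evidence. Sequencing batch stays open, since the log2 difference of at least 3.88 from the 1 sham library of the same batch lies within the range of 5.03 between sham libraries. Also open are ILC3 or T cells that carry type 2 transcripts, gamma-delta T cells among them, and doublets of them with ILC2. A response of ILC2 to the surgery stays open too, a hypothesis from 2 ADX libraries with no adjusted p under the threshold.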

How the results depend on the processing

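The alternatives added after the data were seen were shared barcodes kept, clusters of low UMI count left out, the sequencing batch as a covariate and the first batch alone; the others were planned. Where a value moved, the cause was not tested, except that leaving out a library leaves fewer samples and that no filter on low counts tests more genes. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Of the alternative values of named genes, 687 of 792 kept their direction and side of the threshold; with 1 library left out these were 275 of 346. The others mostly lost the call, 4 and 2 gained it, and none reversed. Shares of cells kept both in 153 of 171 values and, with 1 library left out, in 66 of 85. Genes could not be tested with each library clustered alone in B, ILC2, cDC2, eosinophil and monocyte-like cells, nor in eosinophil-like cells under stricter cell filters or without low-UMI clusters; the sex-matched contrasts without a sham male library have no residual degrees of freedom. Groups of 1 library are assumed to vary like the others. Shallow cells limit shares of cells with a UMI to 2000 UMIs.

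Without a filter on low counts the genes called were 31 in B, 1114 in ILC2, 117 in NK/ILC1, 234 in T, 676 in cDC1, 468 in cDC2, 240 in macrophage, 759 in mast, 322 in mature DC and 321 in monocyte-like cells. DESeq2 called 54 in eosinophil, 181 in macrophage and 83 in monocyte-like cells, and in the ILC2 contrasts 53 (female), 202 (male), 41 (sham sexes) and 3 (difference). Resolution 2 gave 43 and sex as a covariate 64 in macrophage-like cells, and 0 classes for the receptor list. Libraries clustered alone gave 38 in T and 35 in cDC1-like cells. With doublets kept the counts were 5 in B, 415 in cDC1, 51 in mature DC and 84 in monocyte-like cells. With shared barcodes kept they were 28 in B and 68 in monocyte-like cells, and the log2 share ratios −0.14 in ILC2 and −0.89 in macrophage-like cells. Without low-UMI clusters the ratios were 0.10 in NK/ILC1 and 0.087 in cDC2-like cells. Without thinning the cytokine shares were 96.7%, 97.5%, 99.6%, 97.2% and 97.5%.

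With the sequencing batch as a covariate the share ratios were 2.88 in B and 2.03 in eosinophil-like cells, no longer past the threshold, and the genes called 22 in B, 232 in ILC2, 89 in NK/ILC1, 24 in T, 20 in cDC2, 6 in eosinophil, 116 in mast, 55 in mature DC and 8 in monocyte-like cells. Lists passed in 6 classes (glucocorticoid, all lower), 4 (type 2, 2 lower and 2 higher), 2 (alternative activation, both lower), 4 (proliferation, 2 lower and 2 higher), 2 (receptors, 1 lower and 1 higher) and 2 (epithelial, both lower), and the MHC class II list in 4, all lower. The first batch alone gave 28 in B, 80 in NK/ILC1, 22 in T, 46 in eosinophil and 129 in macrophage-like cells, and lists passed in 5 (glucocorticoid, all lower), 5 (type 2, 2 lower and 3 higher), 7 (interferon, 5 lower and 2 higher), 2 (MHC class II, both lower), 5 (proliferation, 2 lower and 3 higher), 0 (receptors) and 3 classes (epithelial, all lower). With an estimated correlation each of the 11 lists passed in 0 classes.

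Leaving out 1 library gave share ratios of 1.53 to 3.59 in B, −0.17 to 0.38 in ILC2, −0.47 to 0.14 in NK/ILC1, −0.68 to 0.13 in cDC2 and 1.29 to 2.26 in eosinophil-like cells. Genes called ranged from 14 to 38 in B, 363 to 1147 in ILC2, 37 to 115 in NK/ILC1, 31 to 155 in T, 49 to 751 in cDC1, 16 to 198 in cDC2, 41 to 144 in eosinophil, 7 to 463 in macrophage, 92 to 692 in mast, 67 to 214 in mature DC and 40 to 127 in monocyte-like cells. Lists passed in 1 to 4 classes (glucocorticoid), 2 to 4 (type 2), 2 to 4 (alternative activation), 2 to 4 (MHC class II), 2 to 4 (T cell effector), 2 to 5 (proliferation) and 0 to 1 (receptors).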

Other observations

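The values of Igkc, Il17a and Xist in this part were chosen after they were seen; the lists were fixed before the data were examined. Interferon-stimulated genes were lower in 4 of 9 classes, NK/ILC1, T, cDC2 and mature DC-like (camera adjusted p from 0.00199 to 0.0268, and adjusted p from 0.425 to 0.589 with an estimated correlation). In the fit with the batch as a covariate they stayed lower in these 4 and were higher in macrophage-like cells (camera adjusted p = 0.00277). In ILC2-like cells Igtp (1.56) rose and the list did not pass (adjusted p = 0.716). Genes of MHC class II, which present antigen, were lower in ILC2, T, eosinophil and mast-like cells (camera adjusted p = 0.0351, 0.0089, 0.0133 and 0.0288, and adjusted p = 0.585, 0.533, 0.585 and 0.581 with an estimated correlation) and higher in macrophage-like cells (camera adjusted p = 0.0268, adjusted p = 0.618 with an estimated correlation). With the sequencing batch as a covariate the list stayed lower in ILC2 and T-like cells and was also lower in B-like (camera adjusted p = 0.0174) and NK/ILC1-like cells (camera adjusted p = 0.0444). The calls in eosinophil, mast and macrophage-like cells ended (camera adjusted p = 0.153, 0.26 and 0.67). In ILC2-like cells H2-Ab1 (−0.78), H2-Aa (−0.77) and H2-Eb1 (−0.78) fell, 3 of 8 members over all genes and 5 adjusted over the list alone; the list's adjusted p ranged from 0.00765 to 0.585 over alternatives, with 0.119, 0.0531 and 0.233 without sham_male replicate 1, sham_male replicate 2 and ADX_Cast_male.

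The T cell effector list was also lower in mast and mature DC-like cells (camera adjusted p = 5.21e-04 and 0.0186, and adjusted p = 0.356 and 0.452 with an estimated correlation), and within the first batch the call in mature DC-like cells ended (camera adjusted p = 0.0874). Of its members in ILC2-like cells Lag3 (1.81) and Havcr2 (1.08) rose and Prf1 (−3.12) fell, and the list did not pass (adjusted p = 0.934). The alternative activation list was lower in T and mast-like cells (camera adjusted p = 0.0313 and 0.0102, and adjusted p = 0.469 and 0.425 with an estimated correlation). The type 2 lymphocyte activation list was lower in mast-like cells (camera adjusted p = 2.77e-06, adjusted p = 0.356 with an estimated correlation) and higher in macrophage-like cells (camera adjusted p = 1.37e-05, adjusted p = 0.515 with an estimated correlation), where Il13 was the member called (1.20) and ILC2-like cells held 478 times more. Under the batch covariate it was also higher in eosinophil-like (camera adjusted p = 0.0314) and lower in NK/ILC1-like cells (camera adjusted p = 0.0114). The steroid and alarmin receptor list was higher in macrophage-like cells (camera adjusted p = 0.0275, adjusted p = 0.425 with an estimated correlation), with 0 of 7 members called over all genes and 1 adjusted over the list alone; within the first batch its call ended (camera adjusted p = 0.194), and with the batch as a covariate it was lower in monocyte-like cells (camera adjusted p = 0.0376).

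Il17a was fitted higher in all 7 classes measured and called higher in 5, cDC1, cDC2, eosinophil, macrophage and monocyte-like; it did not pass in ILC2 (edgeR adjusted p = 0.324) and T-like cells (4.25, SE 1.22, edgeR adjusted p = 0.566). It was called in macrophage-like (log2 3.89, SE 0.42, edgeR adjusted p = 0.00613) and eosinophil-like cells (3.28, SE 0.64, edgeR adjusted p = 0.00532), where gamma-delta T-like cells held 2270 and 26.1 times more over all libraries. Gamma-delta T-like cells made up 0.638% of sham and 0.349% of ADX cells. ILC2-like cells, 9.55% of ADX cells, held Il17a at 954 CPM or more in both ADX libraries. Which class these transcripts came from was not tested. Igkc was higher in mast-like (5.25, SE 0.27, edgeR adjusted p = 1.46e-09) and NK/ILC1-like cells of the ADX libraries (5.08, SE 0.27, edgeR adjusted p = 9.11e-06), and did not pass in B-like cells (0.53, SE 0.18, edgeR adjusted p = 0.354). Barcodes of sham_male replicate 2 found in no other library held Xist at 10.04 CPM, against 0.48 and 0.0 CPM in the other male libraries.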
